A study of Schizosaccharomyces pombe with 2 samples.

How the data were processed

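PolyA RNA of a pat1 prp2-1 strain of Schizosaccharomyces pombe was sequenced from 1 culture kept at 25 °C and from its other part after 1 h at 34 °C, per the labels. The 2 libraries were assigned to temperatures from their titles, and each group holds 1 library. The deposited table gives, per the file headers, whole read counts of spliced and unspliced reads for each intron in each library, without scaling. The authors also deposited the ratio of spliced to unspliced reads, after replacing each count of 0 by 1, per the file headers. A smaller deposited table holds the 1340 introns whose spliced and unspliced reads sum to more than 50 in each library, with the same counts as the full table. All 10748 ratios and all 21496 replaced values matched recomputation from the counts, the ratios within a relative tolerance of 1e-06. TopHat and SAMtools were used, per the submitters' processing notes, with versions not given. The genome build, the annotation, the counting tool, the use of strand and the definition of an unspliced read are not given in the sources used here. It is therefore not known whether an unspliced read crosses 1 exon-intron border or lies anywhere in the intron, and a long intron would gather more reads under the second definition.

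From the counts, the unspliced share of an intron was computed as its unspliced reads divided by its spliced and unspliced reads, in percent. The ratios were not used further, since they carry no depth. Introns with fewer than 20 reads in either library were left out of the main comparisons, 2866 of 5374, among them 161 with 0 reads. The total was 636989 reads at 25 °C and 493659 at 34 °C, and a measured intron had a median of 71 and 78 reads in these libraries. Shares have exact Clopper-Pearson 95% intervals and changes have Newcombe 95% intervals, both for counting error only. Unspliced and spliced reads at the 2 temperatures were compared per intron by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the 2508 measured introns, and introns with an adjusted p under 0.05 were called. Shares are taken within a library, so library size does not enter them.

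Medians have 95% percentile intervals from 10000 bootstrap draws of introns. The median of each of 10 gene groups was placed among 10000 random lists with the same number of introns in each of 10 bins of read depth. The groups were written as lists of gene symbols before the data were examined. Some lists took symbols by prefix besides named genes. The meiotic list took every symbol that starts with mug, meu, mde or rec followed by a digit. The spore formation list took every symbol that starts with wtf followed by a digit. Pairs of introns of 1 gene were compared by the z of the difference of their log odds ratios, with 0.5 added to each count and Benjamini-Hochberg adjustment over 1825 pairs. Introns were named by a rule fixed beforehand: the 12 largest rises and the 8 largest falls among called introns, the deepest called and the deepest uncalled intron of each gene group, the introns of the 3 genes with the widest difference between their introns, and prp2, uaf1 and bpb1. There were no called falls to name.

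Gene symbols, intron positions and sequences came from the NCBI annotation of the ASM294v3 assembly, which may differ from the annotation the authors used. Of 2548 gene identifiers, 2541 had an entry. Introns were placed by their number in 2427 genes whose number of introns equals that of exactly 1 annotated transcript. In 114 genes the number differed and 7 had no transcript, and their introns, among them those of wtf13 and wtf18, have no position here. The direction of numbering was settled from the data. In minus-strand genes the rank correlation of 5' splice site score and change within genes was -0.222 (95% interval from 1000 draws of genes -0.304 to -0.138) with numbers from the left end of the chromosome and 0.0461 (-0.0420 to 0.128) with numbers from the right end. In plus-strand genes it was -0.174 and -0.00256. Introns were therefore numbered from the left on both strands, and the sequence properties in the report were compared over single-intron genes and plus-strand genes, where counting along the chromosome and along the transcript gives the same place. Of 2415 placed introns with enough reads, 1414 overlap an annotated exon of another gene on either strand, and reads of such a gene could have been counted as unspliced.

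Properties were taken from GT-AG introns of at least 30 nt. The 5' splice site score sums, over intron bases 3 to 6, the log2 ratio of the base's frequency among all such introns to 0.25, with 0.001 added to each frequency. The branch site was the best match to CTRAY with the branch point A in its place, in the last 60 nt. Pyrimidines and uridines were counted over 14 bases that end 3 bases before the exon. The outer quartiles of each of 7 properties were compared, and the difference was placed among 10000 shuffles within bins of depth. Branch site matches were split into 5 of 5 against fewer, because most introns had all 5.

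Calling was tested on simulated data with the read depths of the 2508 measured introns. It called 26.9% of 67 introns given a rise of 10 points, 58.2% of 67 given 20 points, 84.8% of 66 given 40 points and 0.173% of 2308 left unchanged. In the data 82.6% of measured introns were called, so the adjustment was stricter in the simulation and its recovery may understate detection. Simulated reads had counting error only, so the false calls there leave out differences between libraries. Alternatives were other read minimums, an adjusted p under 0.01, a minimum change of 10 points, 1 intron per gene, the smaller table, other scalings and pseudocounts, the log2 odds ratio and tertiles. Non-overlapped introns, 1 intron per gene for the groups, and minus-strand genes for the properties were added after seeing the data. Gene expression levels were not analysed here as a comparison, since the tables hold reads at introns only. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.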

Results

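Spliced and unspliced reads were compared in fission yeast (Schizosaccharomyces pombe) cells that carry prp2-1, a temperature-sensitive allele of the gene for the large subunit of U2AF. U2AF is the factor that binds the polypyrimidine tract and the 3' splice site early in spliceosome assembly. The cells were taken through synchronous meiosis, and at the start of meiosis I the culture was divided between 25 °C, where Prp2 works, and 34 °C, where it is inactivated. PolyA RNA was sequenced 1 h later, with 1 library per temperature. The 25 °C library held 595190 spliced and 41799 unspliced reads over 5374 introns of 2548 genes, 636989 in total. The 34 °C library held 296520 spliced and 197139 unspliced reads, 493659 in total. The unspliced share of an intron is its unspliced reads as a percentage of its spliced and unspliced reads, and 2508 introns of 1441 genes had at least 20 such reads in each library. With 1 library per temperature no difference has a replicate check, and a test on reads compares these libraries and not the temperatures in general. Every interval of a share covers counting error only. Reads that are PCR copies of the same molecule are not independent, so these intervals may be too narrow even for counting error.

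The first question was how far inactivation of Prp2 changed splicing across the genome. Unspliced reads made up 6.56% of all intron reads at 25 °C (exact 95% binomial interval 6.50 to 6.62) and 39.9% at 34 °C (39.8 to 40.1). The median unspliced share of the 2508 measured introns was 5.60% at 25 °C (95% bootstrap interval over introns 5.26 to 5.95) and 41.4% at 34 °C (39.9 to 43.4). More than 50% of reads were unspliced in 39 introns at 25 °C and in 990 introns at 34 °C. Per intron, the share rose in 2071 introns (82.6%) and fell in 0 by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment, and at an unadjusted p under 0.05 the same exact test gave 2099 higher and 0 lower. The introns with a rise belonged to 1245 genes.

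The median change was 32.3 percentage points (bootstrap interval over introns 30.8 to 34.2), with quartiles of 15.2 and 51.0 points. The change exceeded 50 points in 660 introns and lay within 5 points of 0 in 227, of which 29 were still called higher. The 437 introns without a call had a median of 109 reads over both libraries, against 168 for the called introns, and at such depths a change of moderate size was not always detectable. The strain carried prp2-1 in both libraries, so an effect of the temperature itself and an effect of losing Prp2 are not separated by this comparison. The median log2 ratio of unspliced reads between the libraries, 34 over 25 °C, was 2.32 (2.29 to 2.39) without scaling and 2.68 when scaled by library totals, with a pseudocount of 1.

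**Figure D1:**
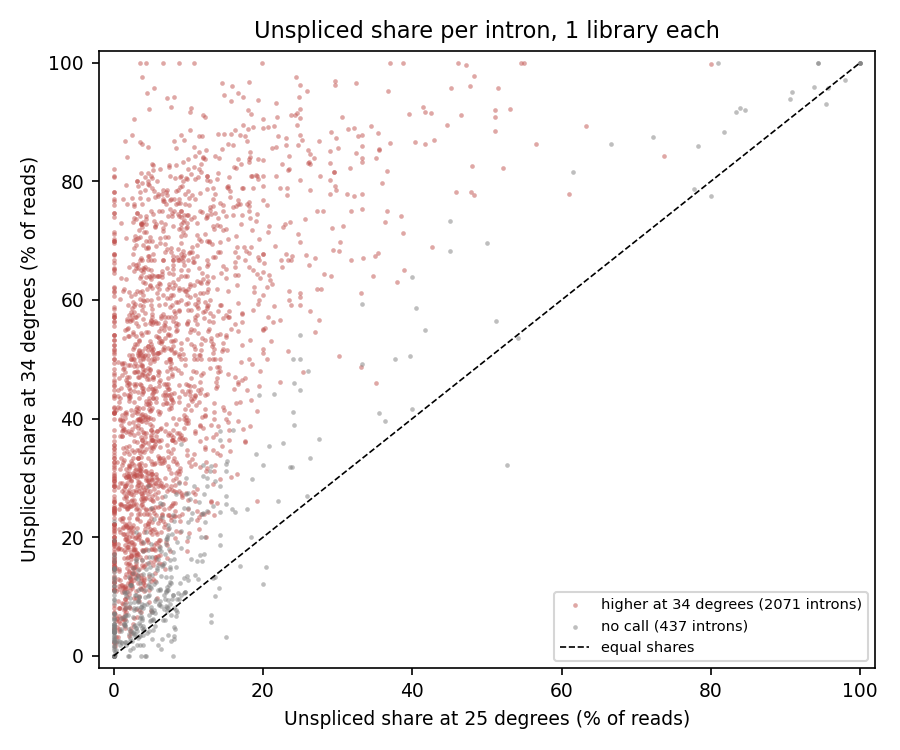
Unspliced share (% of reads) of each measured intron in the 25 °C library (horizontal axis) and the 34 °C library (vertical axis), 1 library each, with 1 point per intron, red for the 2071 introns higher at 34 °C by Fisher's exact test and grey for the 437 without a call. Most points lie above the dashed line of equal shares, and 0 introns were called lower.

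The introns with the widest rises went from nearly complete splicing at 25 °C to nearly none at 34 °C. The deepest of the 12 introns named for their size was intron 3 of spn7, a septin made in meiosis, at 3229867 to 3230017 on chromosome II of the ASM294v3 assembly, within the coding part. Its unspliced share went from 8.06% of 720 reads (exact 95% interval 6.17 to 10.3) to 94.2% of 1754 reads (93.0 to 95.2). Intron 1 of crp79, an RNA-binding protein gene, at 1793952 to 1794022 on chromosome I, went from 5.39% of 167 reads to 95.8% of 449 reads, a change of 90.4 points (Newcombe 95% interval 85.3 to 93.3). Intron 2 of aah2, at 4374259 to 4374376 on chromosome I, went from 7.11% of 211 reads to 94.0% of 282 reads, a change of 86.9 points (81.4 to 90.4). All 3 lie in coding sequence of genes on the minus strand. Of the 12 introns, only that of rhn1 is free of overlap by an annotated exon of another gene, whose reads could have been counted as unspliced.

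The other introns of this group were shallower and their changes less precise. Intron 1 of mta1 had 1 unspliced read of 28 at 25 °C and 24 of 24 at 34 °C, a change of 96.4 points (Newcombe interval 76.7 to 99.4). Intron 2 of glo3, which encodes an ARF GTPase-activating protein, had 1 of 23 reads unspliced at 25 °C and 21 of 21 at 34 °C. Intron 1 of taf51 went from 1 unspliced read of 26 to 78 of 80, and intron 9 of rdh54, a DNA translocase gene of recombination, from 10.7% to 100% of 22 reads. At 34 °C the unspliced share was 100% in intron 1 of ptb1 (21 reads) and in intron 4 of ppk3 (25 reads), 94.9% in intron 1 of lub1, 92.2% in intron 1 of tda3 and 90.5% in intron 3 of rhn1. In each of these introns the share rose by Fisher's exact test, and the largest adjusted p of the 12 was 1.71e-10, for rdh54.

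Prp2 acts with a smaller U2AF subunit and with the branch-point binding protein encoded by bpb1. The table lists 0 introns under the symbol prp2 and 0 under uaf1, a symbol taken beforehand as a partner gene of prp2. The single intron of bpb1 had 2 unspliced reads of 13 at 25 °C and 3 of 45 at 34 °C, which is below the minimum of 20 reads, so it was not tested.

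Introns were next compared between 10 groups of genes fixed before the data were examined. A group is described by the median change of its introns and by the percentile of that median among 10000 random lists of the same number of introns with matched read depth, which describes these libraries and is not a test. No intron of any group was called lower, either over all introns or adjusted over the list alone.

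Introns of cytosolic ribosomal protein genes had the smallest median change of the 10 groups, 18.3 points (bootstrap interval 12.7 to 27.1, 77 introns of 66 genes), at percentile 0.04. The share rose in 59 of the 77, or 58 adjusted over the list alone. The single intron of rpl14 rose from 2.10% of 3292 reads to 3.39% of 4804 reads (adjusted p = 8.13e-04, Fisher's exact test). The intron of rpl35A02 had 7.59% unspliced at 25 °C and 14.6% at 34 °C, a difference that missed the threshold (adjusted p = 0.0578, Fisher's exact test). Many ribosomal protein genes have a near-identical copy, so reads of either could have been assigned to the other.

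Introns of spliceosome and splicing factor genes had a median change of 19.4 points (12.8 to 26.3, 61 introns of 38 genes), at percentile 0.02, with 44 higher, or 41 adjusted over the list alone. Intron 2 of lsm6, for a Sm-like protein of the U6 particle, rose from 5.10% of 667 reads to 29.8% of 578 reads. Intron 3 of srp2, for an SR protein, had 8.07% at 25 °C and 8.02% at 34 °C (interval of the difference -4.48 to 5.27 points). With 1 intron per gene the percentile of this group was 5.76, and over introns that no exon of another gene overlaps it was 4.43, so its place outside the middle 95% of random lists was lost in both.

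Meiotic genes had the highest percentile of the 10 groups. The list named genes of meiotic recombination, the chromosome axis, the meiotic divisions and their regulators. It also took every symbol that starts with mug, meu, mde or rec followed by a digit, by name and not by function. Introns of the list had a median change of 41.0 points (37.3 to 47.2, 86 introns of 48 genes), at percentile 99.8, and the share rose in 82 of 86, or 84 adjusted over the list alone. Intron 2 of spo6, which encodes the regulatory subunit of a kinase needed for meiosis II, was the deepest of them and rose from 1.42% of 7403 reads (1.16 to 1.71) to 49.4% of 17011 reads (48.6 to 50.1). The intron spans 3103933 to 3103978 on chromosome II and is also overlapped by an annotated exon of another gene. Intron 2 of mug64, a gene named for its upregulation in meiosis, had 1.91% at 25 °C and 6.85% at 34 °C and was not called over all introns (adjusted p = 0.0551, Fisher's exact test).

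Introns of cell cycle and chromosome segregation genes had the largest median change of the 10 groups, 41.8 points (36.3 to 53.3, 30 introns of 19 genes), at percentile 88.8, and 28 of 30 rose, the same number as adjusted over the list alone. Intron 2 of cut9, for a subunit of the anaphase-promoting complex, rose from 10.3% of 253 reads to 62.4% of 149 reads. Intron 1 of apc10, for another subunit of that complex, had 3.30% at 25 °C and 9.21% at 34 °C, with an interval of the difference of -1.66 to 14.8 points. Spore formation genes had a median of 34.2 points (14.8 to 44.5, 64 introns of 28 genes), at percentile 81.1, and 49 introns rose, also 49 adjusted over the list alone. The percentile of this group depended on the introns taken, from 7.22 with a minimum of 10 reads to 99.02 with a minimum of 50 reads, and it was 98.1 with 1 intron per gene. The list took every symbol that starts with wtf followed by a digit, besides named genes. The named members of this group were wtf genes, a family of meiotic drivers that kill spores. Intron 2 of wtf13 rose from 7.34% of 17010 reads to 51.9% of 3714 reads, whereas intron 4 of wtf18 had 0.196% of 9710 reads at 25 °C and 0.163% of 3066 reads at 34 °C. The wtf genes share sequence, so the assignment of their reads is uncertain.

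Protein turnover and respiration genes had medians below that of all introns. For proteasome and ubiquitin genes it was 22.2 points (12.3 to 32.1, 79 introns of 39 genes), at percentile 0.92, with 62 higher and also 62 adjusted over the list alone. This place among random lists was lost with a minimum of 50 reads (3.33), for the log2 odds ratio (4.52) and over introns free of overlapping exons (3.79). Intron 2 of rpt1, for a proteasome ATPase, had 5.08% at 25 °C and 6.03% at 34 °C. For mitochondrial respiration and ATP synthase genes the median was 21.3 points (13.9 to 32.0, 58 introns of 30 genes), at percentile 3.80, with 52 higher and also 52 adjusted over the list alone, and the percentile ran from 1.12 with a minimum of 50 reads and 2.27 for the log2 odds ratio to 16.5 with 1 intron per gene, 30.4 over introns free of overlapping exons and 44.2 with a minimum of 10 reads. In qcr6, for a subunit of respiratory complex III, intron 4 rose from 3.995% to 12.3%, and intron 3 had 7.16% at 25 °C and 7.66% at 34 °C.

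Of the other groups, introns of small GTPase and vesicle transport genes had a median change of 24.8 points (17.7 to 27.9, 68 introns of 32 genes), at percentile 11.9, with 60 higher and also 60 adjusted over the list alone. In bet1, which encodes a SNARE of transport between the endoplasmic reticulum and the Golgi, intron 1 rose from 3.47% to 7.77%, and intron 2 had 3.90% of 4818 reads at 25 °C and 4.38% of 1756 reads at 34 °C. Cytoskeleton and motor genes had a median of 25.4 points (13.8 to 31.5, 52 introns of 28 genes), at percentile 9.05, with 38 higher and also 38 adjusted over the list alone, and the percentile ran from 1.46 for the log2 odds ratio to 34.4 with a minimum of 50 reads. The intron of cam1, the calmodulin gene, rose from 4.33% to 18.0%, and intron 1 of fim1, the fimbrin gene, had 5.64% and 9.56%. Heat shock protein and chaperone genes had a median of 28.4 points (17.1 to 38.8, 30 introns of 16 genes), at percentile 29.2, with 23 higher and also 23 adjusted over the list alone. Intron 2 of cct7, for a chaperonin subunit, rose from 1.23% to 6.63%, and intron 1 of cdc37, for a partner of Hsp90, had 2.18% at 25 °C and 0.985% at 34 °C (interval of the difference -4.11 to 1.63 points).

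**Figure D2:**
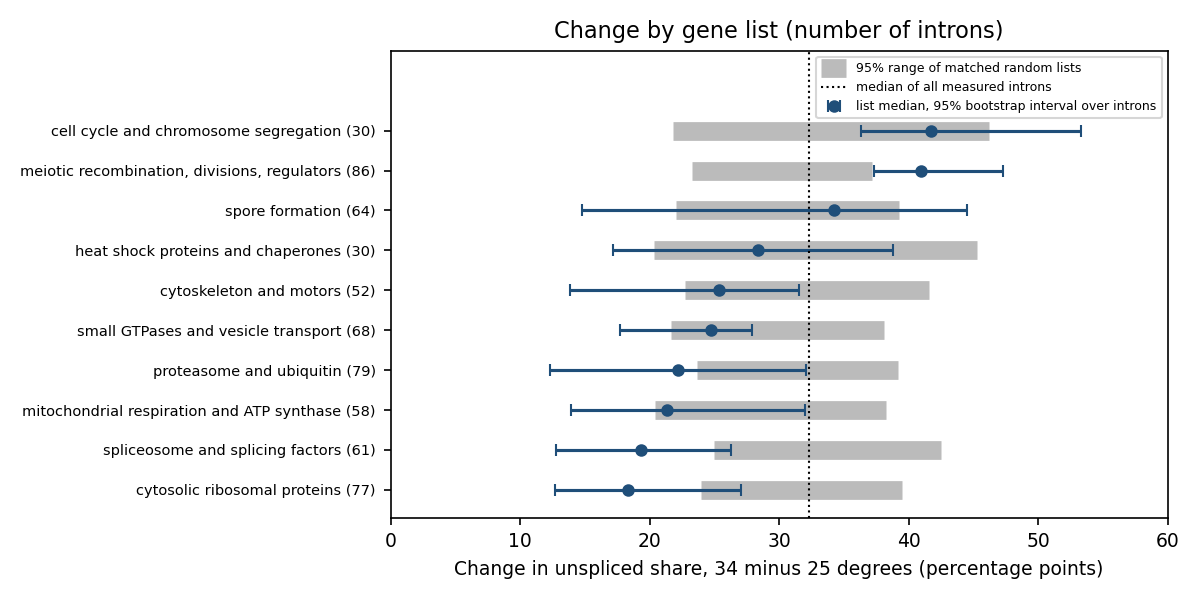
Median change in unspliced share (percentage points, 34 minus 25 °C) of the introns of 10 gene groups, with bars for the 95% bootstrap interval over introns, grey bands for the 95% range of 10000 random lists of matched depth and a dotted line at the median of all measured introns. Ribosomal protein introns lie lowest at 18.3 points, and meiotic introns lie at 41.0 points, above the band of their random lists.

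Whether the introns of 1 transcript responded alike was asked in the 627 genes with at least 2 measured introns, 1694 introns in all. In 429 of these genes every measured intron rose, in 19 none was called, and in 179 called and uncalled introns stood side by side. The widest difference was in ubc4, which encodes a ubiquitin-conjugating enzyme. Its intron 1, at 715453 to 715531 on chromosome II, rose from 1.59% of 315 reads (exact interval 0.517 to 3.67) to 86.8% of 1048 reads (84.6 to 88.8). Its intron 2, at 715610 to 715980, rose from 1.08% of 1394 reads (0.603 to 1.77) to 6.42% of 1930 reads (5.37 to 7.61). Both lie in the coding part. Intron 1 begins with GTAAGT and is 79 nt long, and intron 2 begins with GTATGT and is 371 nt long.

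In SPAC23C4.09c, on the minus strand of chromosome I, intron 3 rose from 8.64% to 78.6% (70.8 to 85.1), whereas introns 1, 2 and 4 had 7.46%, 14.9% and 5.77% unspliced at 34 °C and were not called. In dms1, on the minus strand of chromosome III, introns 1 and 2 rose to 81.3% (78.1 to 84.3) and 80% (63.1 to 91.6), and intron 3 had 7.23% at 25 °C and 9.46% at 34 °C. Introns are numbered here as in the table, from the left end of the chromosome, so the last of these numbers is the first intron of a minus-strand transcript. An annotated exon of another gene overlaps each of the introns of ubc4, SPAC23C4.09c and dms1. Of 1825 pairs of introns from 1 gene, 208 (11.4%) differed in their log odds ratio, by the z of the difference with Benjamini-Hochberg adjustment, and these pairs came from 129 genes (20.6%). The median gap between the introns of a pair was 15.9 points, and 75 genes held a gap above 50 points. With at least 50 reads per library the genes with a differing pair were 35.9% of those compared.

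**Figure D3:**
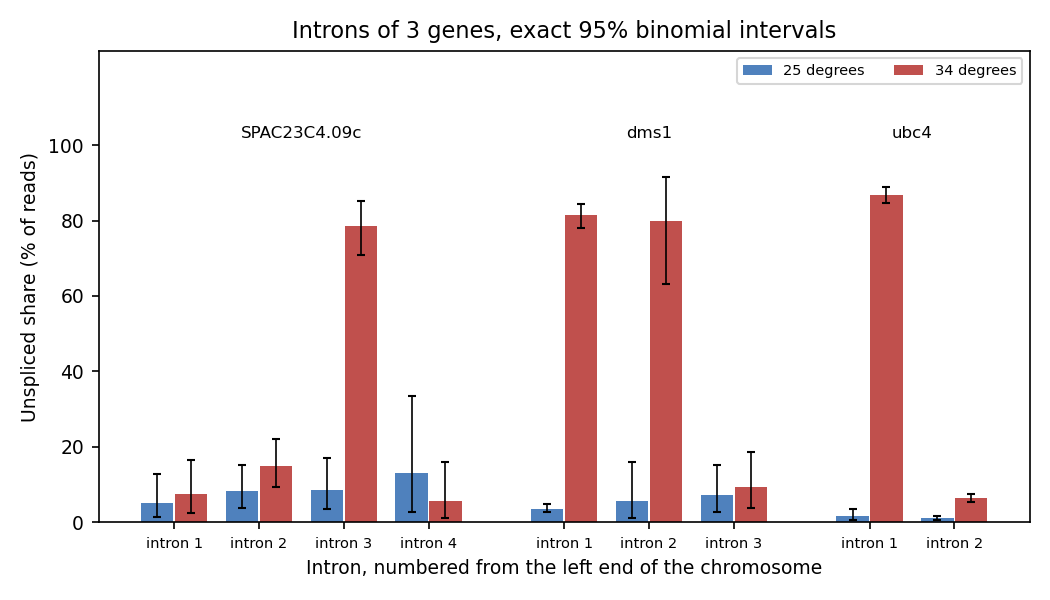
Unspliced share (% of reads) of each measured intron of SPAC23C4.09c, dms1 and ubc4 in the 25 °C library (blue) and the 34 °C library (red), 1 library each, with exact 95% binomial intervals. In ubc4, intron 1 reached 86.8% and intron 2 reached 6.42% at 34 °C.

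The study concerned U2AF and the recognition of the 5' splice site, so the change was set against the sequence of the introns. This was done over 1438 GT-AG introns whose place is the same whether introns are counted along the chromosome or along the transcript. Introns that begin with GTAAGT, the commonest 5' splice site, had a median change of 22.1 points (bootstrap interval 19.5 to 25.3, 439 introns). Those with GTATGT had 29.1 points (25.0 to 34.9, 314 introns), with GTACGT 35.9 points (30.6 to 41.9, 77 introns), with GTATGA 40.6 points (33.9 to 47.6, 85 introns) and with GTATGC 46.2 points (39.1 to 52.7, 52 introns). The order did not follow the 5' splice site score throughout. Introns with GTGAGT (score 1.23) had 22.5 points (14.1 to 50.5, 21 introns). Those with GTAAGA (4.12) had 24.4 points (18.4 to 29.3, 104 introns) and with GTAAGG (2.91) 27.0 points (16.3 to 39.7, 30 introns). These medians lay below that of GTATGT, which has a score of 5.67. The medians of GTAAGT and GTATGC introns at 25 °C were 4.55% and 5.70%, and at 34 °C they were 29.4% and 53.6%.

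A score of bases 3 to 6 of the intron, higher for sites closer to the commonest bases, was lower where the change was larger, with a Spearman rho of -0.259 across introns. The 364 introns with the lowest scores had a median change of 42.7 points (39.7 to 45.04) and the 439 with the highest score 22.1 points. Shorter introns changed more as well (rho -0.202), with a median of 39.4 points (34.9 to 42.9) for the 385 introns of at most 48 nt and 22.4 points (19.0 to 24.6) for the 364 of at least 104 nt. Introns with a higher GC content changed more (rho 0.118), with 35.7 points in the top and 27.7 points in the bottom quartile. All 3 differences between outer quartiles lay outside the 95% range of 10000 shuffles within bins of read depth, which for the score was -5.75 to 5.10 points.

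Properties of the 3' end of the intron showed smaller differences. Introns whose best branch site matched CTRAY (R, a purine, and Y, a pyrimidine) at all 5 bases had a median change of 31.3 points (29.1 to 33.8, 1120 introns), and the other introns 30.9 points (26.4 to 35.2, 318 introns). The share of pyrimidines before the 3' splice site had a rho of 0.00198 and that of uridines 0.00348. Their differences between outer quartiles were -2.91 and -3.02 points, inside the ranges of their shuffles. The outer quartiles of the distance from the branch site to the 3' splice site were bounded at 9 and 13 nt. In many introns the bases counted therefore include the branch site. These values thus cannot decide whether the content of the polypyrimidine tract alone was related to the change. For the distance from the branch site to the 3' splice site rho was -0.0574, at percentile 1.18 of the shuffles, and the difference of outer quartiles was -4.65 points, at percentile 3.39. With a minimum of 50 reads rho (-0.0578) was no longer outside the shuffles, and with tertiles the difference (-4.81 points) was outside them.

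The only intron of a gene had a median change of 26.7 points (23.6 to 29.9, 518 introns), at percentile 0.08 of random lists of matched depth. First introns had 33.6 points (28.6 to 36.9, 307 introns), internal introns 36.2 points (33.1 to 39.6, 287 introns) at percentile 99.4, and last introns 34.8 points (27.9 to 38.2, 326 introns). Introns ending in AAG, CAG and TAG had medians of 32.3, 29.2 and 31.3 points. The 7 sequence properties were compared across introns, which are not independent replicates, and the bases scored and the branch site rule were settled after first looks at these data, so these relations are exploratory.

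**Figure D4:**
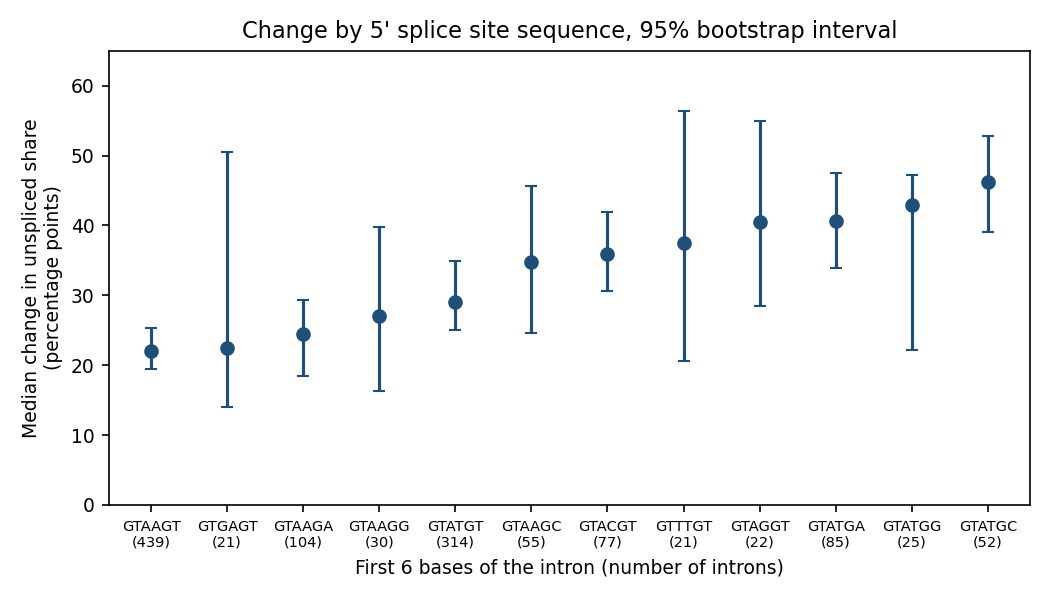
Median change in unspliced share (percentage points, 34 minus 25 °C) by the first 6 bases of the intron, for sites with at least 20 introns, with 95% bootstrap intervals over introns and the number of introns in brackets. GTAAGT introns had the lowest median at 22.1 points and GTATGC introns the highest at 46.2 points.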

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

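The 2866 introns below the minimum of 20 reads were left out of the report's main tests of single introns. Their pooled reads showed a signal above the 25 °C level. Their unspliced share was 11.4% of 28883 reads at 25 °C (exact 95% interval 11.1 to 11.8) and 52.1% of 39054 reads at 34 °C (51.6 to 52.6).

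The rise of unspliced shares in most introns was weighed against 3 other explanations. Reads from overlapping genes counted as unspliced are argued against as the whole cause by a median of 32.6 points (30.05 to 35.1) over the 1001 introns that no exon of another gene overlaps, a set chosen after seeing the data. Genomic DNA in the 34 degree library would add unspliced reads to silent genes too, but at 543 introns with at most 2 spliced reads the median gain was 0 reads, against 28 at called introns. The temperature shift itself rather than Prp2 stays open and cannot be told apart from loss of Prp2 function, because 0 libraries of a strain without the prp2 mutation were analysed here.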

How the results depend on the processing

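Of 127 values under alternatives, 103 kept their side of the threshold or moved by less than their margin, and 0 called values changed direction. The margin for counts and percentages was wide. Without a read minimum, 2789 introns were higher against 2071, and 55.9% against 82.6% of introns, and both values are among the 103. Within the 103, 9 uncalled values changed sides. The percentile of spore formation was 7.22 with a minimum of 10 reads and that of heat shock proteins 56.0 with a minimum of 50. The sign turned for uridines with a minimum of 50 reads (rho -0.00457), for the log2 odds ratio (rho -0.00387) and with tertiles (1.56 points). With minus-strand genes added it turned for uridines (0.814 points), pyrimidines (1.09 points) and branch site matches (-1.11 points, rho -7.30e-04). The percentage of introns called higher ran from 55.9 to 87.7, and 0 introns were called lower in any setting. Fewer introns were higher with a minimum of 50 reads (1195), with 1 intron per gene (1186) and over introns not overlapped by another gene (847, chosen after seeing the data), because fewer were tested (1362, 1441 and 1001). The median change was 28.4 points both in the smaller table and with a minimum of 50 reads. The median log2 ratio of unspliced reads, 2.32 without scaling, was 2.68 scaled by library totals, 2.86 by the median ratio of spliced reads and 2.49 with a pseudocount of 0.5.

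For percentiles of gene groups the cause was not tested. With a minimum of 50 reads, proteasome genes moved inside the middle 95% (3.33), and spore formation (99.02) and mitochondrial genes (1.12) moved outside, whereas with a minimum of 10 reads mitochondrial genes lay near the middle (44.2). For the log2 odds ratio, proteasome genes moved inside (4.52), and cytoskeleton (1.46) and mitochondrial genes (2.27) outside. Among the alternatives chosen after seeing the data, 1 intron per gene brought splicing factors inside (5.76) and spore formation outside (98.1), and introns free of overlapping exons brought splicing factors (4.43) and proteasome genes (3.79) inside. For branch site distance, the correlation came inside the shuffles with a minimum of 50 reads (-0.0578), and the quartile difference went outside with tertiles (-4.81) and with minus-strand genes added (-5.42, chosen after seeing the data). With a minimum of 50 reads, 72 genes had called and uncalled introns, among fewer genes compared, and 35.9% of genes had a differing pair. Separate counts for the 5' and 3' exon-intron junctions and gene-level values were not run, as the tables used give 1 unspliced count per intron. No paired analysis was possible because each temperature has 1 library. Depth may limit calls of small changes. Most introns with a simulated rise of 10 points were missed, but few simulated introns changed, which makes the adjustment stricter than in the data.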

Other observations

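The within-gene test of the 5' splice site and its shuffles were chosen after related values had been seen, and the 3 gene groups tested below were singled out after their percentiles were known, as was the use of 1 intron per gene for the groups, and the fit over single-intron and plus-strand genes was also added after the values were seen. Genes named in the next 3 paragraphs were also chosen after their values were seen.

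Reads at introns also differed between the libraries in number, by gene group. Summed per gene over spliced and unspliced reads and scaled by library totals, the median log2 ratio of 34 to 25 °C was 0.71 over 1813 genes, and scaling by the median ratio of spliced reads adds 0.19 to every value. Spore formation genes had a median of -0.92 (bootstrap interval -1.31 to -0.01, 32 genes), below all 10000 random lists of matched depth, and -0.73 under the other scaling. That list includes the wtf genes, which share sequence, so the assignment of their reads is uncertain. Ribosomal protein genes had a median of 0.97 (0.84 to 1.12, 68 genes), at percentile 99.1. Meiotic genes had 0.03 (-0.23 to 0.42, 55 genes), at percentile 1.09, and -0.72 when spliced reads alone were counted and scaled by the totals of spliced reads. Among genes with at least 1000 reads, mde10 had 7384 reads at 25 °C and 300 at 34 °C (scaled fold 0.0524, interval 0.0466 to 0.0588), and osh6 had 204 and 835 (fold 5.28, 4.53 to 6.19). These are reads at introns in 1 library per temperature and not expression levels.

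Some deeply read introns changed little. Of 193 introns with at least 1000 reads over both libraries, 30 changed by less than 5 points and 79 by more than 30. Small as they were, 18 of the 30 changes were called higher. Intron 3 of cka1, the catalytic subunit of casein kinase 2, had 2.16% of its reads unspliced at 25 °C and 2.52% at 34 °C (interval of the difference -0.41 to 1.33 points). Intron 1 of tef5 had 0.175% and 0.739%, and were not called, whereas the intron of sui1 rose from 0.313% to 2.32%. GTAAGT opened 13 of the 29 such introns with a position, against 439 of the 1438 introns whose sequence properties were compared. The 29 include introns of minus-strand genes with several introns, which the 1438 leave out, and this difference was not tested. Outside this set, the intron of snu6, the U6 small nuclear RNA gene, had 1 unspliced read of 96 at 25 °C and 72.9% of its reads unspliced at 34 °C (exact interval 65.5 to 79.5). Since polyA RNA was sequenced, these reads need not represent the U6 RNA as a whole. In mes1, a regulator of meiosis II, the share was 1.40% at 25 °C and 28.1% at 34 °C (24.4 to 31.9).

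A group of 39 introns was already more than 50% unspliced at 25 °C, and 13 of them rose further. Some of the 39 may not be true introns as placed here. Those of pdc101, rrp36 and new11 had placed lengths of 0, 0 and 2 nt. Those of fta3, med11 and SPAC29A4.02c had 0 spliced reads in both libraries. Intron 3 of vma9 went from 73.7% (70.2 to 77.1) to 84.2% (80.2 to 87.7), and intron 2 of cds1, a checkpoint kinase gene, from 51.1% to 91.9%. Intron 3 of pdc2 had the lowest change of all measured introns, with 52.6% of 38 reads at 25 °C and 32.1% of 56 reads at 34 °C, and was not called. Exons of another gene overlapped 57.6% of the placed introns of this group and 58.6% of all placed introns.

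A hypothesis is that weaker 5' splice sites leave an intron more dependent on Prp2. Differences between genes in expression or mRNA turnover are argued against as the whole cause. Within plus-strand genes the rank correlation of score and change was -0.174 (95% interval -0.256 to -0.089, 795 introns). This lay below the lowest of 1000 shuffles of changes within genes (-0.161), with the lower value of both directions of numbering kept. The shuffles did not redo the choice of the bases scored, which was settled after first looks at these data. Shorter introns having weaker sites are argued against by a partial correlation given length of -0.225 (-0.277 to -0.172), and shares already higher at 25 °C by a correlation of -0.262 (-0.331 to -0.195) among introns under 5% at 25 °C. The relation, by which the numbering was itself judged on both strands, is weak, as the intron with the weaker site rose more in 56.2% of 674 pairs within plus-strand genes and in 57.5% of 845 pairs within minus-strand genes. A temperature effect on weak sites without Prp2 may give the same values and was not tested.

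The smaller changes in ribosomal protein and splicing factor introns and the larger ones in meiotic introns were weighed against 2 explanations, the first by a linear fit on 5' splice site score, log length and intron position over 2403 GT-AG introns, whose places in minus-strand genes rest on the numbering judged by the score. Splicing factors (61 introns) then lay at percentile 0, below all random lists, and meiotic genes (79 introns) at 99.9. Over single-intron and plus-strand genes alone they lay at 2.37 (29 introns), close to the bound of 2.5, and 99.9 (63 introns). This argues against a linear effect of score, log length and position as the whole cause there. The fit cannot decide on the 5' splice site sequence itself, because the change did not follow the score throughout. GTAAGA introns (score 4.12) had a median change of 24.4 points, and GTATGA introns (3.68) had 40.6. The 75 fitted ribosomal protein introns lay at 2.18, against 0.01 before the fit and 0.04 for all 77, past the bound set beforehand. The interval of the median of these 75 (-13.3 to -1.75 points) reached the middle of the range of random lists (-8.89 to 4.70), a requirement added after the values were seen. Over single-intron and plus-strand genes, ribosomal protein introns lay inside the bound (4.68, 66 introns). So 5' splice sites and intron lengths that differ between the lists cannot be told apart there from a difference of their own. Changes in read number between the libraries are argued against as the whole cause for all 3 groups. The percentiles were 0.22 for ribosomal proteins, 0.06 for splicing factors and 99.5 for meiotic genes among random lists matched on that change, over the same 75, 61 and 79 introns. The number counts spliced and unspliced reads together, so it holds the reads that set the unspliced share. A change in the number of transcripts was not tested. Fewer independent genes may still account for the splicing factors, whose percentile was 5.76 with 1 intron per gene, and no biological explanation was tested.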
